A study of Mus musculus with 2 samples.

How the data were processed

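H3K4me1, monomethylation of lysine 4 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of mouse embryos at 12.5 days of development. There were 2 biological replicates, made from pools of 120 and 88 embryos of both sexes, and they formed 1 group with no second tissue, age or treatment. Per the labels, the libraries had fragments of 300 to 500 bp. Because the series holds a single group of 2 pools, p-values below describe these libraries and not the spread between embryos.

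The deposited files were 4 peak lists on mm10 (GRCm38). Peaks were called on each replicate separately and on both together, per the file headers, and a replicated list was derived from the pooled list and both replicates' lists. Per the file headers, replicate 1's list was made with 1 further input file, and those of replicate 2 and of the pool with 2. The peak caller, its version and its threshold were not given in the sources used here. Each peak carried a display score, set by the authors, which was not used. The fold enrichment of a peak over its background is a ratio made by the authors. It was used to describe, rank or filter peaks within a list and to set X-linked against autosomal peaks of one list, and for peaks found in both replicates it was correlated between their 2 lists. The p and q of each peak were deposited as −log10 values, and the weakest peaks had a −log10 p of 2.02 to 2.03. All 105918 replicated peaks had the coordinates of a pooled peak. Of the pooled peaks, 86498 had an overlap of 50% of either peak in both replicates, and all of those were in the replicated list, which also held others. The peak lists hold no read counts, so the depth of each sample is unknown and no counting interval for a peak's height can be given. No Y-linked peak was among the lists, and no peak ended beyond a chromosome end.

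Gene positions came from GENCODE M21 and sequence from the matching GRCm38 assembly, and the 19 autosomes and the X chromosome were used with 21728 protein-coding genes. Each gene had 1 start site, at the outermost start of its annotated span. Alternative start sites and those of non-coding genes were not counted, so peaks at them could fall under exon, intron or intergenic sequence. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9. Overlap of the replicates was the Jaccard index in bp, the shared length over the joint length, set against 200 circular shifts of one list along each chromosome. An overlap of 1 bp counted as shared. Peak location was taken from the midpoint, with promoters defined as 1 kb to either side of a transcription start site (TSS), and was compared with 200 shifts. Around each TSS, the percent of the 50 kb to either side covered by replicated peaks was computed. The median over a gene list was compared with 10000 random lists of the same size, matched in 5 classes of gene density within 500 kb, with members and draws kept over 100 kb apart. These p-values are two-sided and Benjamini-Hochberg adjusted over the 18 lists. The difference between replicates used the same number of strongest peaks from each.

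Motifs were counted in the central 500 bp of replicated autosomal peaks over 1 kb from every TSS used. Controls were as many windows outside all pooled peaks, matched on chromosome and on GC content in bins of 2%. The 95% interval of each ratio came from 1000 bootstraps over the 19 autosomes. The genes named in the text followed a rule, except Smad7 and Bcl9l, which held replicated peaks among the strongest by the authors' p, and the Hox clusters. In each gene list, the 3 members with the highest and the 1 with the lowest coverage were eligible, as were the 10 genes with the highest coverage genome-wide, 1 per 200 kb, and the 10 regions with the most covered sequence after joining replicated peaks over gaps of up to 12.5 kb. The gene lists, the motifs, the tests of the comparisons in the report and this rule were fixed before the data were examined, except the random lists matched on coverage. The alternatives were too, except for 3, which were gene lists restricted to autosomes, TSSs from RefSeq, and motif controls matched also on repeat content. The tests of the X chromosome and of transcription factor genes, and the spacing of the motif pair, were chosen after the results were seen. The comparison of the Hox clusters with shifted peaks was not among the tests fixed beforehand.

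The procedures were tested on simulated data. With peaks shifted at random, 5% of 200 lists of 22 genes had a p below 0.05, and 42% and 100% were detected once 2 and 4 percentage points of coverage were added to every member. For the difference between replicates, the share was 6.5% with nothing added, and 78.5% and 99% with -2 and -4 points added. The simulated replicates were independent shifts of the replicated list, whereas the real replicates shared many of their peaks. Median coverage around genes was 0.984% with the shifted peaks and 3.05% in the data, and most of the lists tested held fewer genes. The shares detected therefore need not hold for the real lists. In 20000 windows of random bases, a motif of 6 bases returned a ratio of 1.01 where none was planted, and with 10% of windows planted the ratios were 1.37 for a true 1.36 and 1.82 for a true 1.76. A motif of 8 bases in 5% of windows returned 4.49 for a true 4.46. The bootstrap intervals of the ratios were not tested on simulated data.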

Results

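H3K4me1, a histone mark found at enhancers and beside active promoters, was profiled in the facial prominences of mouse embryos at 12.5 days, the outgrowths that form the face and jaws. The data were 2 biological replicates, pools of 120 and 88 embryos. Replicate 1 had 152021 peaks covering 2.38% of the sequenced genome, and replicate 2 had 184428 peaks covering 3.37%. The pooled list held 198337 peaks with a median width of 347 bp, and the replicated list held 105918 with a median width of 559 bp, covering 3.04% of the genome. Sequencing depth per sample is unknown, as the peak lists carry no read counts.

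The first question was how far the 2 pools marked the same sequence. The strongest sites were found in both: of the 10% of peaks with the best p in each list, 98.2% in replicate 1 and 96.05% in replicate 2 overlapped a peak of the other replicate. The weakest were shared less often, at 50.7% and 27.6% of the 10% with the poorest p. The strongest replicated peak by the authors' p had its midpoint in an intron of Smad7, an inhibitor of TGF-beta signalling. It lay on chromosome 18 from 75371349 to 75381172, with a fold enrichment of 9.92. The next 2 had their midpoints in introns of Ahdc1 and Bcl9l, the latter a cofactor of Wnt signalling, and had fold enrichments of 8.19 and 8.63. In all, 70.7% of replicate 1 peaks and 53.1% of replicate 2 peaks were shared, against 6.16% and 5.01% after shifting. The Jaccard index was 0.382 against a mean of 0.0155 over 200 shifts (one-sided permutation p = 0.00498, the smallest that 200 shifts can give). Of the 105918 replicated peaks, 87283 overlapped a peak in both replicates' own lists, and the rest overlapped none in at least 1 of them. Across the 87283, fold enrichment had a Spearman correlation of 0.427 and a Pearson correlation of log2 values of 0.472. Peaks are not independent replicates. Requiring 50% of a peak to be covered lowered the shared percentages to 60.9% and 38.7%.

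Pooled peaks entered the replicated list according to their strength. Of the pooled peaks, 53.4% were in the replicated list (exact binomial 95% interval 53.2 to 53.6%, for counting error only). The percentage was 14.6% in the 10% of pooled peaks with the lowest fold enrichment and 99.9% in the 10% with the highest. In 23997 pooled peaks there was no overlap with a peak of either replicate.

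**Figure D1:**
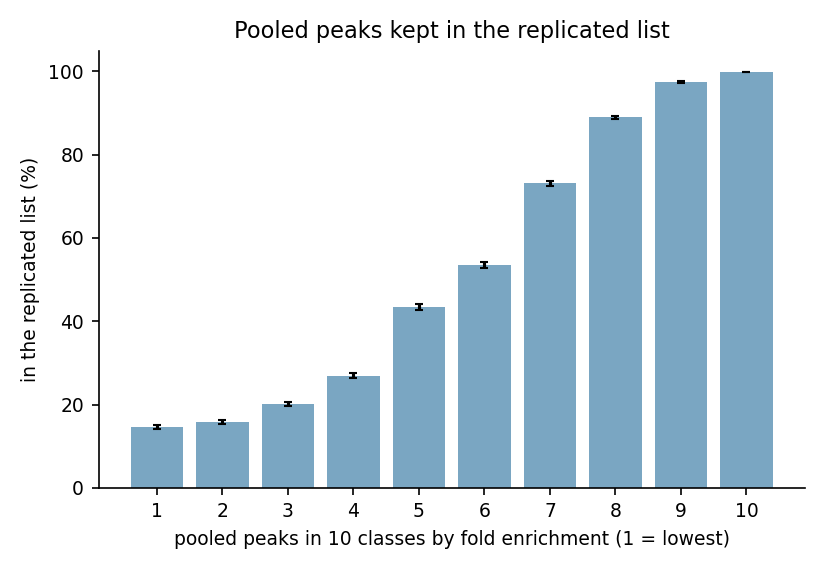
Percent of pooled peaks that were in the replicated list (vertical axis) for pooled peaks in 10 classes of equal size by fold enrichment (horizontal axis), with exact binomial 95% intervals as error bars. The percentage was 14.6% in the lowest class and 99.9% in the highest.

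Most marked sites lay away from promoters. Introns held 52.4% of the replicated peaks and intergenic sequence 33.6%, while exons held 5.53% and promoters 8.47%. The promoter share depended on the cutoff: 8972 replicated peaks lay within 1 kb of a TSS and 19070 within 2.5 kb. The median distance from a peak to the nearest TSS was 33.6 kb, and 41.3% of peaks lay over 50 kb away. Relative to shifted peaks, promoters were overrepresented 5.04-fold (1.68% expected), exons 1.56-fold and introns 1.41-fold, and intergenic sequence was underrepresented at 0.582 of the expected share. Each departure had a two-sided permutation p of 0.00995, the smallest that 200 shifts can give. With promoters taken as 2.5 kb to either side, the ratio to shifted peaks was 4.39 for promoters and 1.17 for exons. Promoter percentages with 1 kb to either side were 7.43% in replicate 1 and 6.99% in replicate 2.

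At start sites coverage dipped near the TSS, between a low upstream shoulder, highest at 15.5% of genes 700 bp away, and a higher downstream peak. The TSS itself was covered in 10.3% of protein-coding genes, against 24.4% on average at 1 to 2 kb downstream and 9.39% at the same distance upstream. Coverage peaked at 29.0% of genes 1100 bp downstream, and far from the TSS, at about 50 kb, it was 4.55%. The ratio of the mean flank at 1 to 2 kb to the centre was 1.64 in the replicated list, 1.70 in replicate 1 and 1.62 in replicate 2. It was above 1 through the downstream side alone, as the upstream flank lay below the centre in each. With 2 samples no test was made.

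**Figure D2:**
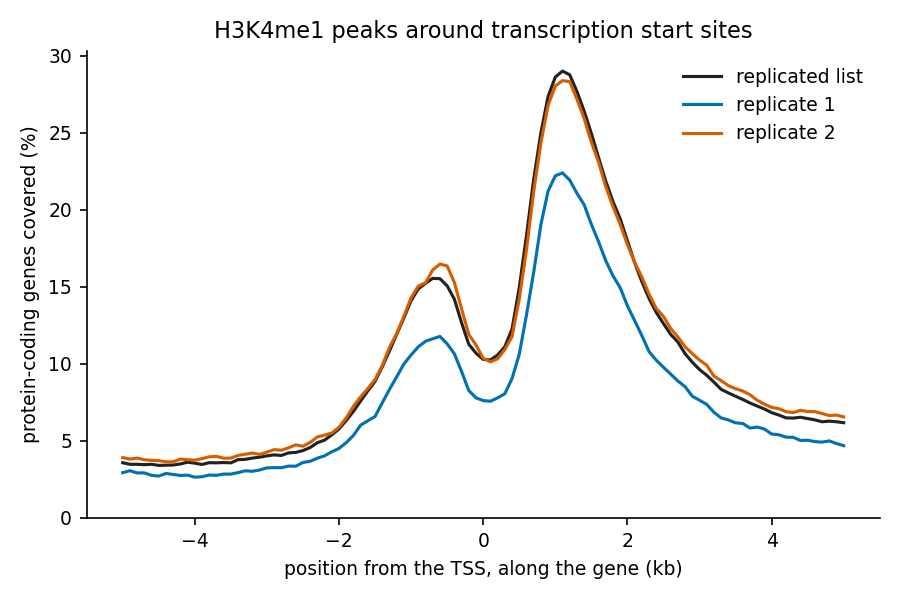
Percent of 21728 protein-coding genes covered by a peak (vertical axis) at each position from the TSS in kb, along the direction of the gene (horizontal axis), for the replicated list and each replicate. All 3 lines dip at the TSS and are highest downstream, at 29.0% of genes in the replicated list.

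The next comparison asked whether genes of facial development had more of the mark around them than other genes. Genes of 4 facial lists did. Transcription factor genes of the facial mesenchyme had a median of 10.05% of the surrounding 100 kb covered, against 2.17% in matched random lists, a 4.64-fold difference, and 19 of the 22 members lay above the median of all genes, 3.05%. Prrx2, a homeobox gene of craniofacial mesenchyme, had 41.8% covered, Alx4, a homeobox gene of the frontonasal region, 35.7%, and Twist2, a basic helix-loop-helix gene, 27.2%. Alx1 was lowest with 0.418%. Genes of the palate and of facial clefts had a median of 9.27% against 2.14%. Mn1 had 36.8%, Fgfr2, a fibroblast growth factor receptor gene, 19.9%, and Foxf1 19.5%, while Tbx22 on the X chromosome had 0%. The annotated TSS of Fgfr2 lay 2857 kb from its RefSeq TSS, at which 32.0% was covered. Jaw and pharyngeal arch patterning genes had a median of 8.26% against 2.33%, led by Dlx3 with 23.1%, its neighbour Dlx4 with 20.9% and Tbx1 with 17.96%, with Isl1 lowest at 1.42%. Facial signalling genes had a median of 7.80% against 2.10%, led by Bmp7 with 28.0%, the hedgehog receptor gene Ptch1 with 25.7% and the Wnt target Axin2 with 25.1%, with Fgf10 lowest at 1.08%. The adjusted p was 0.0009 for the mesenchyme, palate and signalling lists, from the smallest p that 10000 random lists can give, and 0.00288 for the jaw list. In replicates 1 and 2 the medians were 7.01% and 11.4% for the mesenchyme list, 6.98% and 9.91% for the palate list, 6.75% and 10.5% for the jaw list and 6.07% and 8.50% for the signalling list.

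Olfactory receptor genes, which served as a negative control, had few peaks around them. Their median was 0% against 4.63% in random lists (permutation test, adjusted p = 0.0009), and 1006 of 1134 had no replicated peak within 50 kb. Lists of other cell types and tissues did not pass the threshold. Of cell types that the prominences could hold, the permutation test gave no call, and the median was 5.19% for endothelium (random 2.59%, adjusted p = 0.208), 4.84% for surface ectoderm and epithelium (3.24%, 0.539), 4.63% for cartilage and bone (2.61%, 0.324), 4.09% for cranial neurons and glia (2.52%, 0.428), 4.21% for macrophages and white blood cells (3.51%, 0.726), 2.94% for skeletal muscle (2.61%, 0.809) and 1.72% for erythroid genes (3.63%, 0.422). Single genes in these lists were high, among them the endothelial regulator Fli1 with 35.0%, the erythroid regulator Nfe2 with 22.5%, the osteoblast regulator Sp7 with 19.8%, the cartilage collagen gene Col2a1 with 17.3%, the muscle filament gene Des with 19.1%, and Ntrk1, a receptor gene of sensory neurons, with 18.8%. Of other tissues, the median was 4.37% for forebrain and eye (1.97%, 0.153), 3.74% for heart muscle (2.94%, 0.662), 1.90% for liver (2.83%, 0.539), 3.72% for limb and body axis (2.94%, 0.662) and 4.03% for germline and pluripotency (2.84%, 0.539). Housekeeping genes had a median of 5.66% (3.60%, 0.324). With 10 kb to either side of the TSS, the lists of cranial neurons and glia, forebrain and eye, and housekeeping genes also passed the threshold, at 2.87, 2.77 and 2.28 times their random lists.

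**Figure D3:**
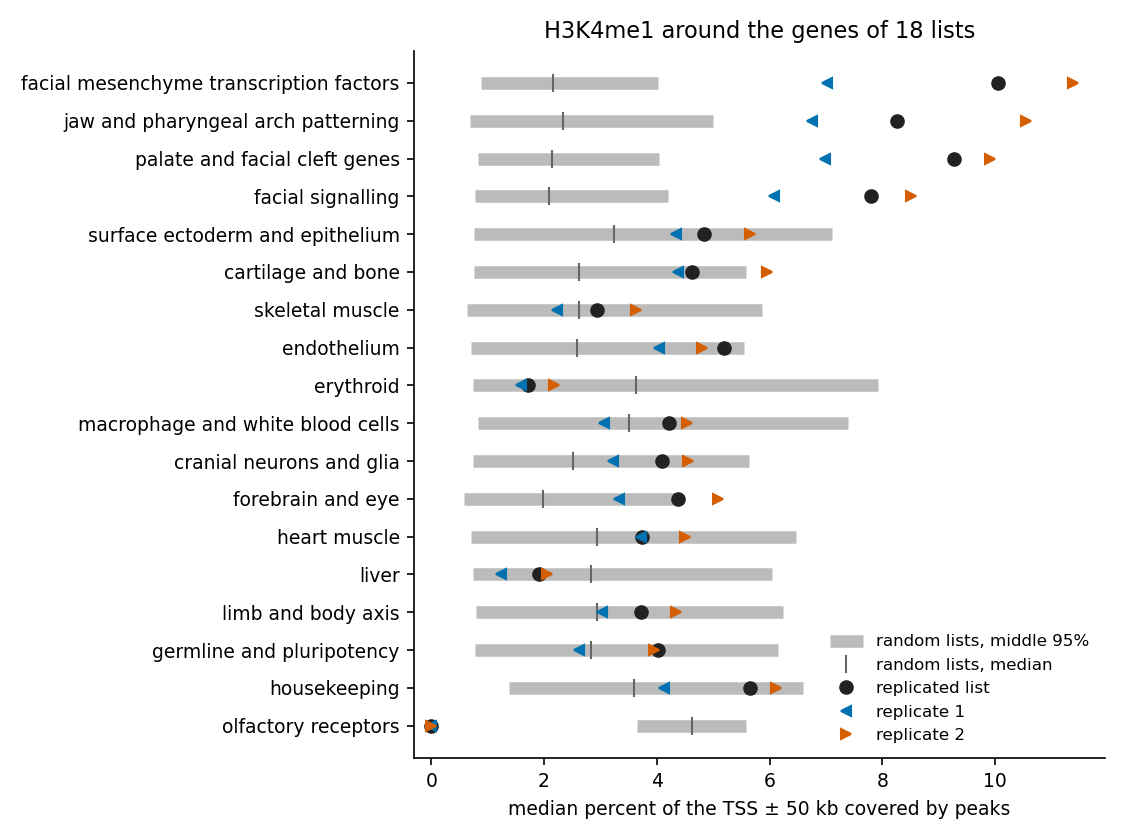
Median percent of the 50 kb to either side of the TSS covered by peaks (horizontal axis) for 18 gene lists (rows), in the replicated list and in each replicate, with the median and middle 95% of 10000 matched random lists for the replicated list. The 4 facial lists lie right of their random lists, at 7.80% to 10.05%, and olfactory receptors lie at 0%.

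Genome-wide, the most densely marked genes were Mrpl23 with 49.2% of the surrounding 100 kb covered, G430095P16Rik with 49.1%, Rara, a retinoic acid receptor gene, with 49.1%, Tcf20 with 48.6%, Bahcc1 with 48.2%, Gse1 with 47.98%, Igsf3 with 46.3%, the corepressor gene Ncor2 with 46.2%, Ski, an inhibitor of TGF-beta signalling, with 45.2%, and Ahdc1 with 45.1%. Joining replicated peaks over gaps of up to 12.5 kb gave 29586 regions. The region with the most covered sequence, 202 kb, lay on chromosome 8 from 120247875 to 120632393, overlapped Gse1 and held the TSS of Gins2. The next had 142 kb covered and held the TSS of Sulf2, and a region with the TSSs of Prdm16, Actrt2 and B230104I21Rik had 138 kb covered. A region that overlapped Rad51b held none of the TSSs used, with that of Zfp36l1 nearest at 76.3 kb, and also had 138 kb covered. The TSSs of 6 genes, Prrx2, Asb6, Ptges, Ntmt1, Cstad and 1700001O22Rik, lay in a region of 344 kb with 127 kb covered. The covered length was 124 kb in a region over Sept9 with the TSS of Gm11733, 115 kb in one over Abr with the TSSs of Nxn, Glod4, Mrm3 and Timm22, and 110 kb at Zfp423. It was 105 kb in a region of 398 kb with the TSSs of Alx4, Cd82 and Gm10803 that also overlapped Ext2, and 104.2 kb in a region of Msi2, whose TSS lay 56.1 kb outside. Mutation of Prdm16 is known to cause cleft palate in mice.

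The X chromosome held few peaks in all 4 lists. Replicated peaks covered 0.124% of the X, and their density was 2.18 per Mb, against 44.1 per Mb over the autosomes and 33.3 per Mb on the autosome with the fewest. Replicate 1 had 3.67 peaks per Mb on the X and replicate 2 had 5.15. No replicated peak lay within 50 kb of 78.9% of X-linked genes, against 18.5% of autosomal genes. Values of X-linked members of the lists can be affected by this. Tbx22, Alas2, Plp1, Cdx4 and Hprt were each at 0%, but not every X-linked member was, with 1 palate gene at 4.68%.

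**Figure D4:**
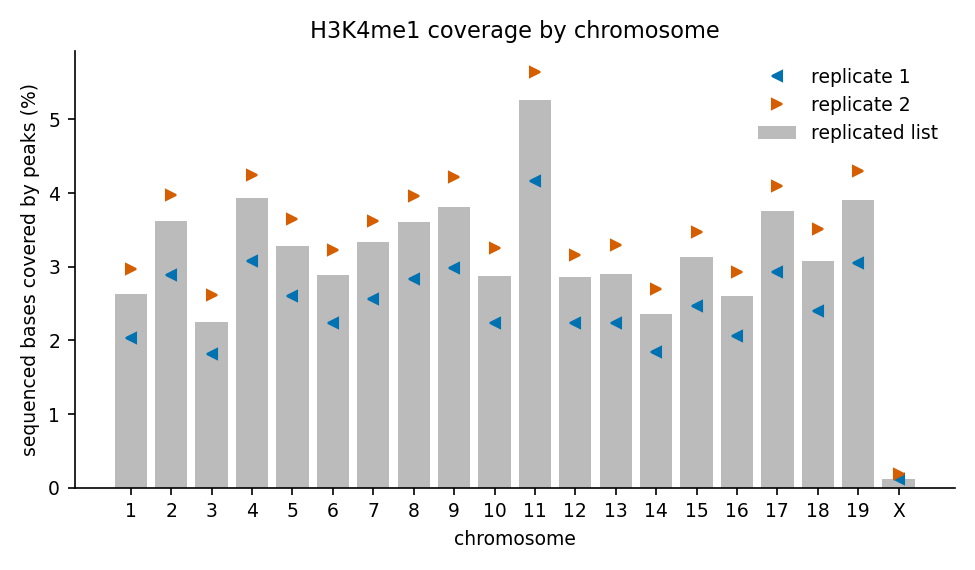
Percent of sequenced bases covered by peaks (vertical axis) for each chromosome (horizontal axis), with bars for the replicated list and triangles for each replicate. The X chromosome lies at 0.124% in the replicated list, below every autosome.

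Coverage around facial genes also differed between the replicates. With the same number of strongest peaks from each, replicate 1 covered more than replicate 2 around 2 of the 22 mesenchyme genes, 3 of 20 palate genes, 2 of 17 jaw genes and 3 of 21 signalling genes. These counts were not particular to facial lists. In the other lists they ran from 0 of 18 for cranial neurons and glia to 5 of 14 for liver. An equal number of peaks need not give equal covered sequence. In the full lists, the median peak width was 295 bp in replicate 1 and 327 bp in replicate 2. The median of replicate 1 minus replicate 2 was -3.63 percentage points for the mesenchyme list (-0.401 in random lists), -2.55 for the palate list (-0.405), -2.25 for the jaw list (-0.422) and -2.22 for the signalling list (-0.400), each with an adjusted p of 0.00072, from the smallest p that 10000 random lists can give. For the other cell type and tissue lists, the adjusted p was 0.322 or more. Olfactory receptor genes had a median of 0 in both replicates, so the lack of peaks fixed their difference at 0 and it does not compare the replicates. This test compared 2 libraries, and the call of the signalling list ended with full lists scaled to each replicate's mean coverage, at a difference from random lists of -0.00936 times that mean (permutation test, adjusted p = 0.964). That of the jaw list ended with 10 kb to either side (permutation test, adjusted p = 0.108), although its difference from random lists was no smaller, at -2.05 against -1.83 percentage points. With random lists matched on coverage in place of gene density, the mesenchyme list passed (permutation test, adjusted p = 0.0036) and the palate (0.0504), signalling (0.217) and jaw (0.504) lists did not.

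Distal peaks, those over 1 kb from every TSS used, were richer in several motifs than control windows of equal GC content. Some of these peaks lay within 2.5 kb of a TSS. The homeodomain motif TAATTA was in 11.8% of 96605 peaks and 7.85% of controls, a ratio of 1.501 (95% interval 1.45 to 1.56), and the TWIST-type E-box CAGATG was at 1.08 (1.07 to 1.09). Both motifs within 15 bp of each other were in 421 peaks and 190 controls, a ratio of 2.22 (1.88 to 2.64). The ratio was 1.37 (1.33 to 1.41) for forkhead, 1.30 (1.26 to 1.33) for TEAD, 1.29 (1.26 to 1.32) for the myogenic-type E-box, 1.23 (1.20 to 1.28) for AP-2 and 5.66 (3.72 to 9.19) for the full NFI site, which was in 164 peaks and 29 controls. The SOX motif was rarer in peaks, at 0.859 (0.825 to 0.891). The intervals also lay above 1 for CTCF, 1.24 (1.12 to 1.38), RUNX, 1.09 (1.07 to 1.12), the nuclear receptor half-site, 1.08 (1.05 to 1.11), and AP-1, 1.06 (1.03 to 1.08). The intervals for GATA, 0.992 (0.949 to 1.03), ETS, 0.903 (0.810 to 1.02), and HNF4, 1.06 (0.952 to 1.18), included 1, and HNF1 was in 2 peaks and 0 controls. Against flanking windows of lower GC content (44.7% against 49.0% in peaks), the homeodomain ratio turned to 0.885, AP-1 to 0.955 and RUNX to 0.880, ETS was at 1.48, GATA at 0.875 and the pair of both motifs at 1.44 (1.28 to 1.62). Repeats made up 13.4% of the sequence in peak windows and 30.7% in the GC-matched controls. With controls also matched on repeat content, the intervals of AP-1 (0.968), GATA (0.942), ETS (0.885) and HNF4 (0.846) lay below 1. Those of the nuclear receptor half-site (0.983) and CTCF (0.978) included 1. The ratio fell to 1.08 for AP-2, 1.21 for the myogenic-type E-box and 3.90 for NFI, and rose to 2.39 for the pair of both motifs. In the central 200 bp with GC-matched controls, CTCF was at 0.691 (0.576 to 0.838).

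**Figure D5:**
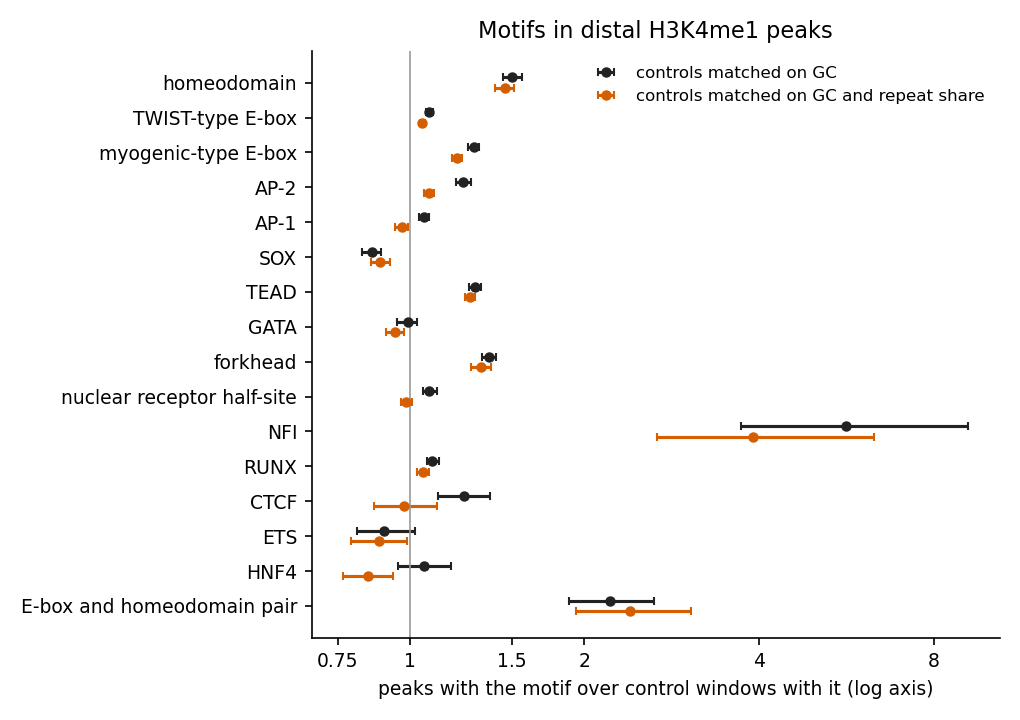
Ratio of distal peaks with a motif to control windows with it (horizontal axis, logarithmic) for each motif (rows), with 95% intervals from 1000 bootstraps over the autosomes, for controls matched on GC content and for controls matched on GC and repeat content. The paired E-box and homeodomain motif lies at 2.22 and the SOX motif at 0.859 with GC-matched controls.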

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

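Of 362 values under an alternative, 334 kept their side of the threshold or stayed within their spread. For gene lists, differences between replicates and motifs, a change of direction was counted only where the main or the alternative value passed the threshold. The macrophage list, which did not pass, ranged from 0.250 to 1.40 times its random lists without being counted as changed. The autosomal lists, RefSeq TSSs and repeat-matched controls were chosen after the data were seen. The Jaccard index ranged from 0.364 to 0.392, the promoter ratio from 4.14 to 5.05, and the mesenchyme list from 3.28 to 4.68 times its random lists. All 4 facial lists passed the threshold under every alternative run for them. The overlap and correlation need both replicates, so leaving out 1 gave no value for them.

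With 50% of a peak covered, 60.9% of replicate 1 and 38.7% of replicate 2 peaks were shared and the rank correlation was 0.481. With a −log10 q of at least 2, the correlation was 0.404 and the replicated share 60.02%. The TSS flank ratio was 1.52 in the pooled list and 1.62 to 1.70 with 1 replicate left out. With 10 kb to either side, cranial neurons and glia (2.87), forebrain and eye (2.77) and housekeeping genes (2.28) newly passed. Differences between replicates, relative to random lists, lost the threshold for the jaw list (-2.05, against -1.83) at 10 kb and for facial signalling (-0.00936) with scaled full lists. Those of olfactory receptors, whose own median of 0 was fixed by the lack of peaks, were 0.125 at 10 kb and 0 with scaled full lists. They newly passed for housekeeping genes at 10 kb (-2.54) and for cartilage and bone at 100 kb (-1.12).

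Against flanking windows, homeodomain (0.885), AP-1 (0.955) and RUNX (0.880) fell below 1, ETS rose to 1.48, GATA reached 0.875 and the motif pair fell to 1.44. With repeat-matched controls, the interval of AP-1 (0.968) lay below 1, those of HNF4 (0.846), GATA (0.942) and ETS (0.885) newly excluded 1, and those of the nuclear receptor half-site (0.983) and CTCF (0.978) newly included it. In the central 200 bp, CTCF was at 0.691. Flanking windows were not matched on GC content, and they also differed in repeat content (27.3% against 13.4% in peaks). The cause of these changes was not tested. Without read counts, differences in depth between the replicates cannot be separated from differences in the mark.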

Other observations

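In this part, the tests of the X chromosome and of transcription factor genes, and the spacing of the motif pair, were chosen after the result was seen. The tests of gene length and of the level were set before their results were seen. The comparison of the Hox clusters was not among the tests fixed beforehand.

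The paired motif had a preferred arrangement. Of 62 arrangements of TAATTA and CAGATG, with gaps of 0 to 30 bp and either order, TAATTA placed 4 bp before the E-box was in 48 distal peaks and 6 GC-matched controls. The other 61 arrangements had a median of 12 peaks and at most 20. With controls also matched on repeat content, that arrangement was in 1 control.

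Coverage of the Hox clusters, which pattern the body axis behind the face, lay within the range of shifted peaks. Replicated peaks covered 4.74% of the Hoxa cluster (median over shifts 0.443%), 1.75% of Hoxb (3.24%), 2.71% of Hoxc (0.977%) and 7.73% of Hoxd (1.60%). As much was covered in 39, 124, 69 and 30 of 200 shifts. Coverage of a single region varied widely over shifts, so this comparison cannot tell raised from ordinary coverage.

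Facial gene lists had more H3K4me1 peak coverage around them than random lists. Regulatory genes in general could have this property, which is argued against as the whole cause. Transcription factor genes of the 4 facial lists had a median of 8.84% covered (48 genes) against 4.35% for those of the other lists (77 genes, two-sided permutation p = 1.0e-04). A narrower choice of genes tried first gave 9.83% against 4.28%. A part of the difference could still come from being a regulator, as the median of all autosomal genes was lower, at 3.29%. That part was not tested. Gene length is argued against too, since with random lists matched on length and gene density the highest adjusted p of the 4 lists was 0.00216. A facial origin of the difference stays a hypothesis, as no other tissue was measured and the genes were listed for their known roles.

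The X chromosome held far fewer peaks than the autosomes. A low number of genes is argued against, since the X had 0.0510 times the replicated peaks per Mb of chromosome 18, the autosome nearest to it in genes per Mb. The loss of X sites whatever their strength, as a filter could produce, is argued against as the whole cause: of X peaks with a fold enrichment of 2.5 or more, 8.81% in replicate 1 (exact binomial 95% interval 6.45 to 11.7%) and 12.96% in replicate 2 (10.3 to 16.1%) reached 3.5, against 21.4% and 23.4% on the autosome with the lowest percentage. A lower X signal read against one calling threshold stays open: X peaks were weaker, but scaling autosomal fold enrichment by the one factor that gives the X density at 2.5 left 5.01% and 5.18% reaching 3.5, below both intervals, and error in the fold enrichment itself was not modelled. Whether 1 active X per cell, fewer X copies in males or less of the mark per copy had a part was not tested.

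Facial lists gained more coverage in replicate 2 than random lists did. Differences that grow with the level could produce part of this: with random lists matched on coverage, the difference from random lists shrank from -3.23 to -1.93 percentage points for the mesenchyme list (permutation test, adjusted p = 0.0036), from -2.15 to -1.09 for the palate list (0.0504), from -1.82 to -0.844 for the signalling list (0.217) and from -1.83 to -0.707 for the jaw list (0.504). The calls of the last 3 ended as the random medians moved to between -1.55 and -1.37 and their middle 95% widened, for the palate list from -1.03 to 0 before and from -2.23 to -0.790 after. With 1 of the 4 lists past the threshold at a smaller difference, the outcome lay between those set for and against this explanation. The further input files, 1 for replicate 1 and 2 for replicate 2, go with the replicates and cannot be told apart from the pools, and no biological explanation was tested.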
